A study of Glycine max with 6 samples.

How the data were processed

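Chromatin immunoprecipitation with sequencing (ChIP-seq) uses an antibody to recover DNA that was crosslinked to a protein, and maps the recovered fragments along the genome. Per the labels, embryos at the early maturation stage, when the seed begins to fill with reserves, came from 6 to 7 mm seeds of the soybean (Glycine max) cultivar Williams 82. Chromatin was fixed in 1% formaldehyde and sheared to fragments of 100 to 500 bp. It was precipitated with 3 µg of an antibody against a peptide of residues 302 to 316 of GLYMA.06G314400 or with 2 µg of an antibody against residues 1 to 15 of GLYMA.13G317000. Each protein had 2 biological replicates, and 2 further samples were input, that is, sheared chromatin that was not precipitated. Libraries were amplified with 15 PCR cycles, per the labels.

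Bowtie 0.12.7, a short-read aligner, and MACS2, a caller of enriched regions (peaks), are named in the submitters' processing notes. The MACS2 version, the genome build, the control used for each call, and the treatment of duplicate reads and of reads that match several places are not given in the sources used here. These steps decide which repeated or duplicated parts of the genome can hold a peak at all, and soybean carries many duplicated segments. The authors deposited 1 list of peaks per precipitated sample, so replicates were called separately and were not pooled. Each peak has a deposited fold enrichment, a ratio of the pile of fragments at its summit to the local background. Each also has a deposited −log10 p and a deposited −log10 q, and the position of its summit. The deposited score was 10 times −log10 q as a whole number, with a difference of 1 in 15 peaks. Every list ended near a q of 0.01, and no list held overlapping peaks. The number of reads behind each list is not given in the sources used here, so the depth is unknown and a missing peak is not evidence of missing binding. The fold enrichments are the authors' values. They were used to describe peaks, to rank or filter them within a list, to order the regions of a protein by the lower value of its replicates, and, as ranks, to compare lists. Values of both proteins at a region are given side by side, without a comparison of height.

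Peaks of 2 lists were paired by an overlap of at least 50% of the shorter peak. Within each protein, pairs of peaks from the replicate lists, ranked by −log10 p, were fitted with the irreproducible discovery rate (IDR), a Gaussian copula mixture that separates pairs ranked alike in both replicates from pairs that are not. Pairs at an IDR of 0.01 or less were kept as reproducible regions, each the union of its pair of peaks. The fit converged after 1030 iterations for GLYMA.06G314400 and after 401 for GLYMA.13G317000. It was tested on simulated pairs of which 70% were reproducible. For 48925 pairs, as for GLYMA.06G314400, it recovered 90.7% of these with 1.04% false calls. For 38236 pairs, as for GLYMA.13G317000, it recovered 90.2% with 1.10% false calls. The simulated pairs came from the kind of mixture that the fit assumes. These rates therefore check the routine and are not error rates of the regions reported here. The overlap routine was checked against direct comparison of all intervals on chromosome 16, where 2139 of 2139 gave the same answer.

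A region was called shared if it overlapped a reproducible region of the other protein by at least 50% of the shorter. It was called specific to a protein if no peak in either list of the other protein touched it. All remaining regions, which met a peak of the other protein that was not reproducible, were called undecided. Overlaps were compared with 100 random placements of the regions on their own chromosomes, by a one-sided permutation test whose smallest possible p is 0.0099, and with 100 local shifts of 20000 to 100000 bp. Both proteins may have been called against the same inputs, and noise shared in this way adds to an overlap. It cannot be simulated from peak lists, so the overlap of lists with different replicate numbers was computed as well. Peaks and regions are not independent replicates. With 2 lists against 2, an exact permutation test, the test used for peak number, cannot give a p under 0.333. No test of peak height between the proteins was made.

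The tests, the overlap limit and the rule for naming items were set before the data were examined. The rule named genes, but no genome sequence or annotation of the build of the peaks was used here. The gene table at hand, with 59048 genes, belongs to an assembly that cannot be matched to the peaks, and 0 of its genes carry the identifier of either protein. Target genes, the position of regions relative to genes, DNA motifs and enrichment of gene lists are therefore not analysed here. The rule was applied to regions in place of genes. Per protein it took the 4 shared regions with the highest lower value of the fold enrichments in both replicates, and the 5 such regions specific to that protein. Summit distances, distribution along chromosomes, spacing, equally long lists of single replicates, patterns of presence over the 4 lists, differences in rank, local shifts, placed chromosomes alone and omission of a single library were chosen after the data were examined. Chromosome length was taken as the furthest peak end, and the outer part of a chromosome as 20% of that length at each end. Means over the 20 chromosomes were tested against 40% by a two-sided permutation test of sign changes with 100000 resamples. Coordinates count from 1 and are those of the authors' files. Alternatives were an IDR of 0.05, no IDR, a q of 1e-05 or less, ranking by fold enrichment, an overlap of 1 bp, summits within 100 bp, equal numbers of regions, same-numbered lists, and omission of each replicate. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.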

Results

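Binding sites of the soybean proteins GLYMA.06G314400 and GLYMA.13G317000 were mapped in early maturation embryos of the cultivar Williams 82 by ChIP-seq. The data held 4 lists of peaks, from 2 biological replicates per protein, and the 2 input samples had no list of their own. The question was where in the genome each protein binds, and the design allows the sites of both to be compared in the same tissue. GLYMA.06G314400 had 60812 peaks in replicate 1 and 53281 in replicate 2. GLYMA.13G317000 had 58036 and 41859 peaks. The mean was 57046.5 ± 5325 peaks (SD, n = 2) for GLYMA.06G314400 and 49947.5 ± 11439 (SD, n = 2) for GLYMA.13G317000, a difference within the spread between replicates (exact permutation p = 0.667, two-sided, n = 2 per protein; the smallest possible is 0.333). Within each replicate number GLYMA.06G314400 had the longer list, but the test did not use the numbers as pairs. The read depth behind the lists is unknown. Replicate 2 of GLYMA.13G317000 was the shortest list, with the narrowest peaks (median 373 bp, against 422 to 512 bp in the others) and the smallest covered length (17.3 Mb, against 26.4 to 36.2 Mb).

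Most peaks of both proteins recurred between replicates at nearly the same positions. Of the replicate 1 peaks of GLYMA.06G314400, 80.5% overlapped a replicate 2 peak, and 94.9% of replicate 2 peaks overlapped a replicate 1 peak. For GLYMA.13G317000 these shares were 65.9% and 93.3%. Random placement gave 3.93% of replicate 1 peaks for GLYMA.06G314400 and 2.5% for GLYMA.13G317000 (permutation p = 0.0099 for each, one-sided, the smallest possible). Fold enrichments of paired peaks correlated between replicates across peaks, which are not independent, with a Spearman rho of 0.906 over 48925 pairs for GLYMA.06G314400 and 0.808 over 38236 pairs for GLYMA.13G317000. Summits of these pairs lay a median of 20 bp apart for GLYMA.06G314400 and 21 bp apart for GLYMA.13G317000. Median fold enrichment within the lists was 5.96 and 7.18 in replicates 1 and 2 of GLYMA.06G314400, with peaks reaching 48.4 and 82.3. In the lists of GLYMA.13G317000 the medians were 5.54 and 5.38, and the highest peaks reached 48.7 and 54.6.

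At an IDR of 0.01, GLYMA.06G314400 had 28720 reproducible regions and GLYMA.13G317000 had 15832. They covered 22.7 Mb and 10.96 Mb, with median widths of 722 bp and 633 bp. Scaffolds outside the 20 chromosomes held 163 regions of GLYMA.06G314400 and 85 of GLYMA.13G317000. The kept regions were 58.7% of the peak pairs of GLYMA.06G314400 and 41.4% of those of GLYMA.13G317000. These numbers depend on the IDR step, since all overlapping pairs come to 48925 and 38236.

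Nearly all reproducible regions of GLYMA.13G317000 were also reproducible regions of GLYMA.06G314400. Of the 15832 regions of GLYMA.13G317000, 15737 (99.4%) were shared, 95 were undecided and 0 were specific to that protein. Of the 28720 regions of GLYMA.06G314400, 15535 (54.1%) were shared, 13060 (45.5%) were undecided and 125 (0.435%) were specific. Among the undecided regions of GLYMA.06G314400, 11262 (86.2%) touched a peak in both GLYMA.13G317000 lists, but these peaks formed no reproducible region. Whether such peaks failed the pairing or the IDR was not separated. A further 1772 held a peak only in replicate 1 of GLYMA.13G317000, and 26 only in replicate 2. Random placement gave an overlap of 1.55% for GLYMA.06G314400 and 2.80% for GLYMA.13G317000, and local shifts gave 2.79% and 5.10% (permutation p = 0.0099 in each case, one-sided, the smallest possible). The size of the shared part changed when a library was left out, but the remaining list of that protein then entered whole, without IDR, so the number of regions changed as well and the effect of the library alone is not separated. In this way, the share of GLYMA.06G314400 regions was 30.0% without its replicate 1, 25.7% without its replicate 2, 93.4% without GLYMA.13G317000 replicate 1 and 99.5% without GLYMA.13G317000 replicate 2, and the share of GLYMA.13G317000 regions was 51.8% without its replicate 2.

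Whether a GLYMA.06G314400 region was shared went with its strength. Among 10 groups of about equal size, ordered by the lower fold enrichment of both replicates, 3.90% of the weakest group was shared, 43.9% of the fifth, 85.0% of the seventh and 99.8% of the strongest. The median lower fold enrichment was 16.3 in shared regions, 7.60 in undecided ones and 6.10 in specific ones. For GLYMA.13G317000 the shared part was 98.3% in the weakest group and 99.9% in the strongest. With the 15832 best regions taken from each protein, 86.2% of the GLYMA.06G314400 regions and 87.5% of the GLYMA.13G317000 regions were shared. At this length 0 regions of either protein were specific. The shares of 54.1% and 99.4% given above thus depend on the different numbers of regions of the proteins. The 15832 best peaks of single lists overlapped by 90.3% between the replicates of GLYMA.06G314400 and by 85.3% between those of GLYMA.13G317000. Lists of different proteins overlapped by 81.1% to 85.9% at that length. The overlap between proteins thus reached into the range of the replicates of GLYMA.13G317000 and stayed below that of GLYMA.06G314400. Fold enrichments of paired peaks from lists of different proteins had a Spearman rho of 0.790 to 0.882 across peaks, within the range of 0.808 to 0.906 between replicates except for the lowest, that of GLYMA.06G314400 replicate 1 with GLYMA.13G317000 replicate 2.

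**Figure D1:**
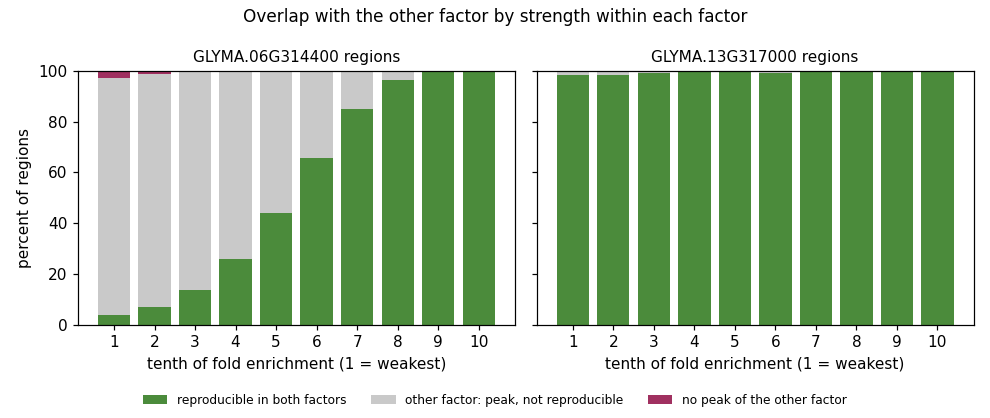
Bars show the percentage of reproducible regions in each of 10 groups of fold enrichment (1 is the weakest), separately for each protein, by class: shared with the other protein, undecided, or specific. The shared part of GLYMA.06G314400 regions goes from 3.90% to 99.8%, and that of GLYMA.13G317000 regions is 98.3% or more in every group.

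The strongest shared regions of GLYMA.06G314400 lay on 4 chromosomes, and each was also strongly enriched with GLYMA.13G317000. The genome build is not given in the sources used here, and genes at these positions are not analysed here. The region on chromosome 9 from 42939018 to 42940424 had fold enrichments of 48.4 and 52.2 in replicates 1 and 2 of GLYMA.06G314400, and of 41.7 and 26.0 in those of GLYMA.13G317000. On chromosome 13, the region from 20717860 to 20718876 had 47.5 and 57.3 with GLYMA.06G314400 and 37.2 and 28.7 with GLYMA.13G317000. The region on chromosome 14 from 6718132 to 6719282 had 47.5 and 51.8, against 42.9 and 31.6 with GLYMA.13G317000. On chromosome 15, the region from 22027473 to 22029016 had 47.4 and 50.5, against 32.9 and 24.4 with GLYMA.13G317000. The summits of both proteins in these regions lay 21, 22, 16 and 16 bp apart, in the order given.

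The strongest shared regions of GLYMA.13G317000 were 4 other regions. The first, on chromosome 18 from 2683094 to 2684464, had fold enrichments of 44.5 and 44.6 with GLYMA.13G317000 and of 44.4 and 66.9 with GLYMA.06G314400. The region on chromosome 8 from 21316468 to 21317491 had 44.8 and 42.3 with GLYMA.13G317000 and 45.3 and 70.2 with GLYMA.06G314400. On chromosome 4, the region from 11188648 to 11189550 had 41.9 and 41.5, against 43.9 and 67.5 with GLYMA.06G314400. On chromosome 17, the region from 12028260 to 12029613 had 46.3 and 40.6, against 42.6 and 64.2 with GLYMA.06G314400. Summits of the proteins were 3, 12, 5 and 8 bp apart in these regions.

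The 125 regions specific to GLYMA.06G314400 were weak. Their lower fold enrichment reached at most 8.48, 79 of them fell in the weakest of the 10 groups, and 0 lay in the upper 5 groups. The region on chromosome 18 from 56614743 to 56615256 had fold enrichments of 10.4 and 8.48 in replicates 1 and 2. On chromosome 13, the region from 45355298 to 45355669 had 8.20 and 8.48. The region on chromosome 17 from 6008903 to 6009486 had 8.05 and 8.22, that on chromosome 1 from 39628017 to 39628544 had 8.34 and 7.92, and that on chromosome 3 from 35384661 to 35385125 had 8.46 and 7.74. The count was 574 at an IDR of 0.05 and 4018 without IDR. It was 6047 without GLYMA.06G314400 replicate 1 and 10400 without GLYMA.06G314400 replicate 2, where the remaining list entered without IDR, and 1897 without GLYMA.13G317000 replicate 1, whose peaks then no longer counted against specificity. The count of 0 regions specific to GLYMA.13G317000 became 1994 without IDR, 4364 without its replicate 1 and 5325 without its replicate 2. Of the 95 undecided regions of GLYMA.13G317000, 94 held peaks in both GLYMA.06G314400 lists. The strongest of these, on chromosome 9 from 42404853 to 42405512 and singled out after its values were seen, had fold enrichments of 25.4 and 23.4 with GLYMA.13G317000 and of 20.8 and 34.6 with GLYMA.06G314400.

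In shared regions, the summits of the proteins lay as close together as the summits of replicates, to within 2 bp of the median. Over 15532 shared regions the median distance between the proteins was 15 bp (quartiles 7 and 27 bp) in replicate 1 and 16 bp (8 and 30 bp) in replicate 2. Between the replicates of GLYMA.06G314400 it was 14 bp (6 and 25 bp), and between those of GLYMA.13G317000 15 bp (7 and 29 bp). Summits lay within 50 bp of each other in 92.4% and 90.0% of regions between the proteins, and in 93.3% and 91.8% between the replicates of GLYMA.06G314400 and GLYMA.13G317000. Distances over 200 bp between the proteins occurred in 1.26% of regions in replicate 1 and 1.96% in replicate 2. Between the replicates of GLYMA.06G314400 and GLYMA.13G317000 they occurred in 1.16% and 1.03%, so such distances were more frequent between the proteins. Replicates were paired by the overlap of single peaks and the proteins by that of the wider regions, so the pairing may add to this difference. Lists of different replicate numbers gave medians of 16 and 15 bp.

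**Figure D2:**
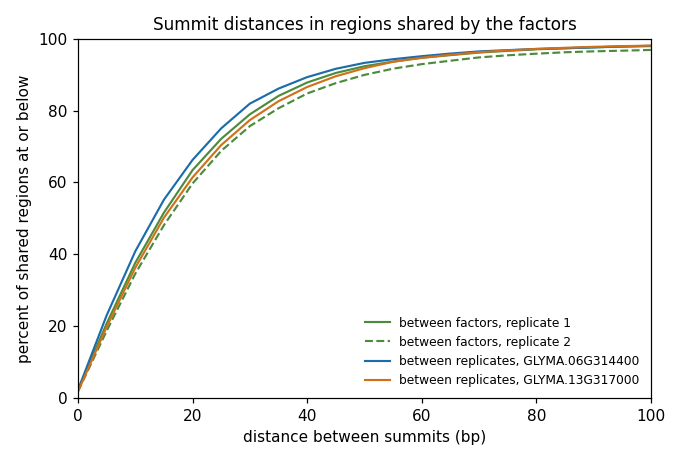
Lines show the percentage of the 15532 shared regions (vertical axis) whose summits lie at or below a given distance in bp (horizontal axis), between the proteins in each replicate and between the replicates of each protein. The 4 lines run close together, with medians from 14 to 16 bp.

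Regions of both proteins were concentrated towards the ends of the chromosomes. The outer 20% at each end, which make up 40% of the length, held 70.03% ± 10.9 of the GLYMA.06G314400 regions and 69.9% ± 10.8 of the GLYMA.13G317000 regions (SD over 20 chromosomes). The share was above 40% on 19 of 20 chromosomes for each protein (permutation p = 2e-05 for each, two-sided, the smallest that 100000 resamples can give). It was highest on chromosome 4, with 86.3% and 86.2%. Chromosome 13 was the exception, with 33.4% for GLYMA.06G314400 and 33.2% for GLYMA.13G317000. The 40% rests on length alone, and repeats or places where reads cannot be mapped were not considered. With all peaks merged into loci, the outer parts held 68.4% of loci with a peak in all 4 lists. They held 67.1% of loci in both replicate 1 lists alone and 55.6% of the 63 in both replicate 2 lists alone. The trait was thus not particular to reproducible regions. The difference between the proteins, GLYMA.13G317000 minus GLYMA.06G314400, was −0.14 percentage points on average (SD 0.92 over 20 chromosomes, positive on 6, permutation p = 0.511, two-sided). As 99.4% of the GLYMA.13G317000 regions were also GLYMA.06G314400 regions, a small difference was largely given in advance.

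Density per chromosome was 30.5 ± 6.28 regions per Mb for GLYMA.06G314400 and 16.8 ± 3.70 for GLYMA.13G317000 (SD over 20 chromosomes). Chromosome 13 was the densest for both, with 2069 GLYMA.06G314400 regions (45.1 per Mb) and 1172 GLYMA.13G317000 regions (25.6 per Mb), followed by chromosome 11 with 41.4 and 23.9 per Mb. Chromosome 1 was the sparsest, with 23.0 and 12.6 per Mb. For each GLYMA.06G314400 region there were 0.513 to 0.581 GLYMA.13G317000 regions per chromosome. Of 956 windows of 1 Mb, 27 held no GLYMA.06G314400 region and 73 held no GLYMA.13G317000 region, while the fullest windows held 104 and 63.

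**Figure D3:**
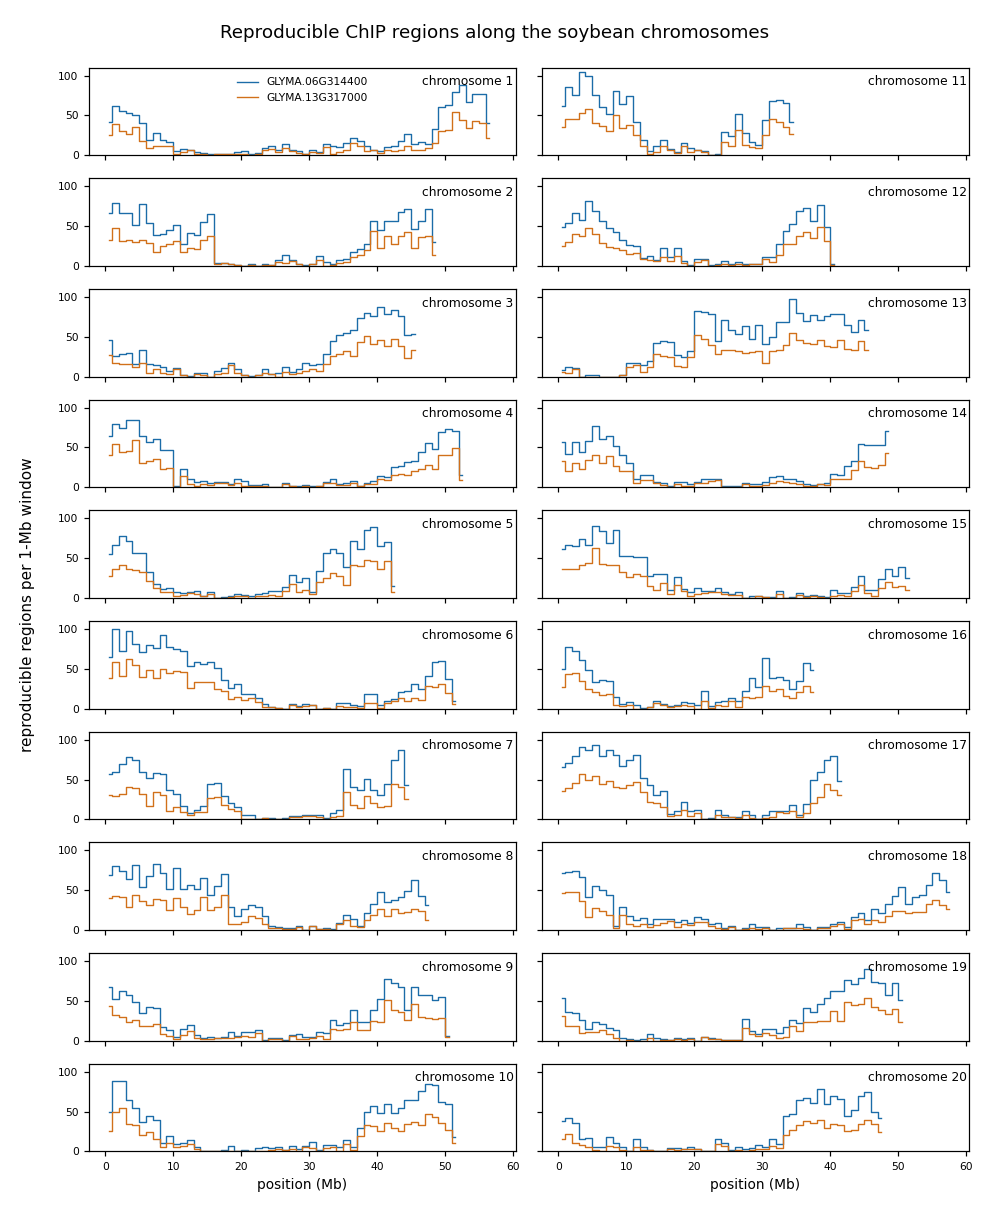
Lines show the number of reproducible regions per window of 1 Mb (vertical axis) along each of the 20 chromosomes (horizontal axis, position in Mb) for both proteins. On 19 of 20 chromosomes the outer 20% at each end hold more than 40% of the regions, and on chromosome 13 both lines are low near the start and high towards the end.

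On a finer scale, the fullest windows of 100000 bp held several times the mean of 3.01 regions for GLYMA.06G314400 and 1.66 for GLYMA.13G317000. For GLYMA.06G314400 they lay on chromosome 11 from 9300001 to 9400000 and from 33300001 to 33400000, with 18 regions each, and on chromosome 8 from 45700001 to 45800000, with 17. These windows held 11, 8 and 9 regions of GLYMA.13G317000. For GLYMA.13G317000 the fullest windows held 12 regions each and lay on chromosome 4 from 1600001 to 1700000, on chromosome 6 from 1600001 to 1700000 and on chromosome 10 from 47700001 to 47800000, with 15, 14 and 13 regions of GLYMA.06G314400. Neighbouring regions were a median of 12136 bp apart for GLYMA.06G314400 and 22587 bp apart for GLYMA.13G317000, against 22506 bp and 40748 bp with uniform placement. A neighbour within 2000 bp was found for 18.3% of GLYMA.06G314400 regions and 11.95% of GLYMA.13G317000 regions. Local shifts gave 19.7% and 11.7% (permutation p = 1.0 and 0.267, one-sided). Each region was shifted on its own and could come to overlap another, unlike the peaks within a list. The comparison therefore cannot decide whether regions cluster at this distance.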

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

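Omission of single libraries, local shifts, placed chromosomes alone and the alternatives for rank differences were chosen after the data were examined. The overlap between the proteins exceeded random placement under all 17 settings, the reported one included (permutation p = 0.0099, the smallest possible), although its size ranged from 25.7% to 99.5% of GLYMA.06G314400 regions and from 51.8% to 100.0% of GLYMA.13G317000 regions. It was 59.6% and 98.5% at an IDR of 0.05, 69.7% and 91.4% without IDR, and 52.7% and 95.7% with summits within 100 bp. These shares thus stayed above random placement without keeping their size, and 30 counts of regions changed by more than 1.5 times or away from 0. Without IDR there were 48925 regions of GLYMA.06G314400, 4018 of them specific, and 38236 of GLYMA.13G317000, 1994 of them specific. With a q of 1e-05 or less in place of IDR these were 47912 and 3677, and 37325 and 1831. At an IDR of 0.05, 574 and 2 regions were specific; ranking by fold enrichment gave 2 specific to GLYMA.13G317000, and equal numbers gave 0 specific to GLYMA.06G314400. Omitting a replicate or library gave 28720 to 60812 regions for GLYMA.06G314400 and 15832 to 58036 for GLYMA.13G317000, with 151 to 17786 and 0 to 6198 specific regions. By construction, the remaining list of a protein enters whole, without IDR, and an omitted list no longer counts against regions specific to the other protein. The share of replicate 1 peaks that recurred was 76.8% to 80.6% for GLYMA.06G314400 and 62.9% to 66.0% for GLYMA.13G317000 under the alternatives.

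With the replicate number as a block, that is, overlap within same-numbered lists only, 74.4% of GLYMA.06G314400 peaks and 87.8% of GLYMA.13G317000 peaks were shared. The labels share a replicate number and a short tag in the sample description between the proteins, with 2 pairs, and do not say what the tag marks, so a common harvest or batch is neither stated nor excluded. As a hint from the data, differences in rank between replicates 1 and 2 correlated at 0.455 between the proteins, at 0.231 by −log10 p, and at 0.505 in regions whose summits lay within 100 bp. An input used as control for both proteins within a replicate number could give such a correlation as well, and the controls are not given. The 35 alternatives set for target genes, position relative to genes, motifs and gene lists were not run, because those results are not analysed here. Read depth is unknown, so peaks missing from a list, above all from replicate 2 of GLYMA.13G317000, set no limit on binding.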

Other observations

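The counts of presence over the lists and the differences in rank were chosen after the data were examined. Of the tests in this part, that on the overlap between the proteins was chosen only after the result was seen. Merging all peaks gave 70952 loci, of which 34119 (48.1%) had a peak in all 4 lists. A further 10513 loci had a peak in every list except replicate 2 of GLYMA.13G317000. Peaks in both lists of one protein and neither list of the other were found at 4025 loci (5.67%) for GLYMA.06G314400 and at 1998 (2.82%) for GLYMA.13G317000, and peaks in both replicate 1 lists alone at 4334, against 63 in both replicate 2 lists alone. Loci of one protein alone were weak, with a median lower fold enrichment of 3.67 for GLYMA.06G314400 and 3.50 for GLYMA.13G317000, and 0 of either kind reached 10 in both replicates. The strongest loci of GLYMA.13G317000 alone, picked after their values were seen, lay on chromosome 10 from 47313271 to 47313824 (fold enrichments 8.67 and 15.5), on chromosome 12 from 2504692 to 2505186 (7.88 and 10.1) and on chromosome 10 from 42013612 to 42014126 (7.81 and 11.4).

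Within the 34070 regions with matched peaks in all 4 lists, counted otherwise than the merged loci above, some ranked higher with one protein than with the other in both replicates. Ranks by fold enrichment were taken among these regions, separately for each list, and put on a normal scale. The mean difference between the proteins was at least 1 in 538 regions in favour of GLYMA.06G314400 and in 826 in favour of GLYMA.13G317000. By the same fold enrichments, 1215 regions differed by that much between the replicate numbers, and 212 by the interaction of protein and number, which stands for noise. By −log10 p, 1397 regions differed between the proteins, 521 between the replicate numbers and 224 by the interaction. In the 29695 regions whose 4 summits lay within 100 bp, by fold enrichment, these counts were 1003, 1004 and 101, so the proteins differed no more often than the replicate numbers. Regions higher with GLYMA.06G314400, named after their values were seen, were on chromosome 2 from 44985928 to 44987116 (fold enrichments 6.36 and 10.9, against 2.84 and 2.96 with GLYMA.13G317000) and on chromosome 15 from 42820268 to 42820899 (7.40 and 10.6, against 2.87 and 3.35). Regions higher with GLYMA.13G317000 were on chromosome 13 from 20727948 to 20728529 (7.89 and 7.76, against 3.22 and 2.63 with GLYMA.06G314400) and on chromosome 18 from 40894313 to 40894937 (7.01 and 13.99, against 3.34 and 3.59). Both kinds occurred on all 20 chromosomes. In every region named here, the protein with the lower values ranked in the lowest 5.71% in each of its lists. These examples thus set a higher-ranked peak of one protein against one of the weakest peaks of the other.

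These rank differences between the proteins correlated at 0.470 between the replicates, across regions, which are not independent. After removal of trends with region strength and peak width the correlation was 0.469, so a trend with width did not account for it. Ranks on the same normal scale for every list leave little trend with strength to remove, so the value cannot decide on strength. Different summits merged into wide peaks did not account for the correlation either, as it was 0.492 in regions whose 4 summits lay within 100 bp. The rank difference between the proteins correlated at 0.0047 between neighbouring regions 10 to 50 kb apart. Fold enrichment is a ratio to the local background, so copy number or coverage that differs over such distances could cancel in it. The value therefore cannot decide whether such differences contribute. Copy number or input coverage that differs only at the region itself would leave no such correlation and was not tested. A hypothesis is that the proteins may occupy part of their shared regions to different extents. Background or cross-reaction particular to each antibody would give the same values and remains open, and sequence preference was not tested.

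The near-complete overlap of GLYMA.13G317000 regions with those of GLYMA.06G314400 could come from noise of an input shared within a replicate number. Over all peaks, those of different numbers overlapped 0.964 times as often as those of the same number (84.6% against 87.8%). These means hide opposite directions. Replicate 1 peaks of GLYMA.13G317000 overlapped at 89.1% with the same number and at 80.7% with the other. For its replicate 2 peaks these were 86.5% and 88.5%. The lists also differ in length. Most GLYMA.13G317000 peaks thus also overlapped across different numbers. The control of each call is not given, however, so a different number need not mean a different input. The comparison also covers all peaks and not the reproducible regions, so it cannot size the part of such noise in their overlap. Open and untested are 1 pooled input for all calls, chromatin that any precipitation enriches, antibodies that recover a common signal by cross-reaction, and binding of both proteins at common sites.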
